A study of Caenorhabditis elegans with 9 samples.

How the data were processed

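ChIP-seq was performed on L4 hermaphrodites of a strain carrying PES-1 tagged with EGFP and 3xFLAG. Per the labels' protocols, synchronised worms were grown at 20 °C on HB101 bacteria, crosslinked with 2% formaldehyde and sonicated; part of the extract was kept as input and the rest precipitated with affinity-purified goat anti-GFP. The 9 libraries were grouped by the labels into ChIP of replicate 1 (2 libraries), input of replicate 1 (4) and ChIP of replicate 2 (3); input of replicate 2 was not analysed here. The labels call them replicates but do not state how many worm cultures they came from.

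The authors deposited 3 peak lists, made with PeakSeq on WormBase WS190 per the file headers and the method column; its version, the aligner, the threshold, the control used for each list and the way the combined list was made are not given in the sources used here. Each peak has a chromosome, start, end and q-value, and the q-value is the authors', as deposited. All q-values are under 0.01, so weaker regions are absent from every list, and a region missing from a list is not shown to be unbound. A q-value depends on depth and control as well as on enrichment, so q-values of different lists are compared only as given. Each list was tied to a replicate by its name, which is the stem of that replicate's sample titles. The libraries of a replicate were not called separately, so there is no spread between libraries, and read depth is unknown.

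The files were read with Python 3.11.15 and pandas 2.3.3, and tests used numpy 2.4.6 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. Peaks within a list never overlapped. Peaks were called shared at an overlap of at least 1 bp. Chance overlap came from 1000 circular shifts of one list along each chromosome, which keep widths and spacing. Chromosome lengths were taken as the last peak end over the 3 lists, since no genome of the build was used. For X against autosomes, chance was 1000 uniform draws over the chromosomes; for the autosomal centres, the middle of 3 equal parts was compared with 1000 uniform draws. Because peaks cluster, intervals come from 2000 draws (1000 for the comparison over strata of q) of 500 kb blocks within each chromosome (percentile, 95%, or 99.2% where the replicates' shares of peaks per chromosome are compared). Exact binomial intervals (Clopper-Pearson, 95%) cover counting error only. The score for correlation was −log10 of the q-value, tested over mutual best overlaps with 100000 permutations of the pairing. With 1 list per replicate, these tests compare lists; they do not measure the spread between worm populations.

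The overlap, correlation, X and centre tests were fixed before the data were examined, as was the rule for named regions. The block intervals, the breakdowns by chromosome and by rank and the window counts were added afterwards. The rule was the 10 combined peaks with the smallest q among those overlapping both replicates. Planned comparisons with promoters, fixed gene lists and the forkhead motif were not run, because the gene table supplied is on assembly WBcel235 and not on WS190, and coordinates were not carried between builds. The routines were tested on simulated data. A simulated shared share of 60.9% over 3000 peaks was recovered as 60.9%, an X to autosome ratio of 0.5 over 8000 peaks as 0.503, a centre share of 50% over 8000 peaks as 49.3%, and a correlation of 0.7 over 2000 pairs as 0.668. Alternatives were other overlap rules, the 50% of each list with the smaller q, lists cut to equal size, uniform placement as chance, single replicate lists, covered length in place of peak number and the middle 50% of each chromosome. Leaving out chromosome I, and keeping only peaks of at least 50 bp, were added after seeing the data.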

Results

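PES-1 is a forkhead transcription factor of the nematode Caenorhabditis elegans. Its binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in hermaphrodites at L4, the last larval stage. The worms carried a pes-1 transgene fused to GFP and FLAG tags, introduced by bombardment together with an unc-119 rescue gene, and chromatin was precipitated with a goat antibody to GFP. The labels describe 9 libraries. Biological replicate 1 has 2 ChIP and 4 input libraries, input being the DNA of an extract before precipitation, and biological replicate 2 has 3 ChIP libraries. Each library has its own extraction number, and these numbers match no input to a ChIP library. The deposited lists hold peaks per biological replicate and 1 combined list, not values per library, so each replicate enters below as a single list. The peak lists carry no read counts, so the depth behind each peak is unknown. Positions are on WormBase genome build WS190; gene annotation of that build was not used here, so regions are named by position.

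The first question was where the tagged protein was bound in each replicate. Replicate 1 gave 3488 peaks with a median width of 374 bp, covering 1696 kb or 1.69% of the genome length spanned by the lists. Replicate 2 gave 4185 peaks with a median width of 308 bp, covering 1523 kb or 1.52%. The combined list held 7213 peaks with a median width of 336 bp, covering 3039 kb or 3.03%. Every peak in the 3 lists had a q value under 0.01. Peaks with a q below 1e-10 numbered 537 in replicate 1, 295 in replicate 2 and 1326 in the combined list. A q depends on depth and control as well as on enrichment, so a smaller q in 1 list than in another is not a measure of stronger binding. Regions wider than 2000 bp numbered 76 in the combined list, 44 in replicate 1 and 13 in replicate 2. The widest combined peak spanned 8856 bp on chromosome X, from 6737036 to 6745891.

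The 10 most significant combined peaks found in both replicates lay on all 6 chromosomes, 5 of them on chromosome III. The strongest region of all 3 lists was on chromosome III from 7709628 to 7712483, a 2856 bp peak with a combined q of 2.67e-233. Its q was 1.42e-136 in replicate 1 and 9.11e-123 in replicate 2, first in both. The next was on chromosome III from 1936510 to 1939403, with a combined q of 2.33e-147, ranking 9 in replicate 1 and 4 in replicate 2. A 719 bp peak on chromosome II from 10174045 to 10174763 ranked 2 and 3 in the replicates, with a combined q of 9.62e-119. On chromosome III, the peaks at 1616169 to 1617189, 10758925 to 10759437 and 7497878 to 7498747 had combined q values of 1.47e-94, 1.39e-86 and 4.66e-82. The peak on chromosome V from 723822 to 728295 was the widest of the 10, at 4474 bp, with a combined q of 1.08e-84. It ranked 11 in replicate 1 and 8 in replicate 2. The peak on chromosome IV from 1419859 to 1420568 ranked 7 and 19.

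A pair of the 10 regions ranked outside the best 20 of replicate 2. The 4394 bp region on chromosome I from 9379946 to 9384339 had a combined q of 1.54e-129 and ranked 12 in replicate 1 and 242 in replicate 2, with a best −log10 q of 41.3 and 11.01. The 2614 bp region on chromosome X from 16929378 to 16931991 had a combined q of 5.78e-87 and ranked 3 in replicate 1 and 72 in replicate 2, with −log10 q of 65.7 and 19.0. Of the 10 regions, 9 had the smaller q in replicate 1, the exception being the chromosome III region at 1936510. At a reciprocal overlap of 50%, 8 of the 10 were still matched in both replicates; the regions on chromosome III at 1936510 and on chromosome I at 9379946, each called as 2 peaks in both replicates, were not. No single region was tested between replicates, since each list gives 1 value per region and no counts.

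The second question was whether the replicates bound the same regions. Of the replicate 1 peaks, 2360 of 3488 overlapped a replicate 2 peak by at least 1 bp, a share of 67.7% (95% interval from 500 kb blocks, 66.1 to 69.3%). Of the replicate 2 peaks, 2396 of 4185 overlapped a replicate 1 peak, or 57.3% (55.5 to 58.9%). Moving the other list around each chromosome gave mean shares of 3.71% ± 0.33 (SD of 1000 shifts) and 3.14% ± 0.29. The observed shares were 18.3-fold and 18.2-fold above these (one-sided permutation p = 0.001 each, the smallest that 1000 shifts can give). The most significant regions were almost always shared. Among the best 500 peaks, 489 of replicate 1 (97.8%) and 492 of replicate 2 (98.4%) were found in the other list, while among the 10% of peaks with the largest q the shares were 38.5% and 25.4%.

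**Figure D1:**
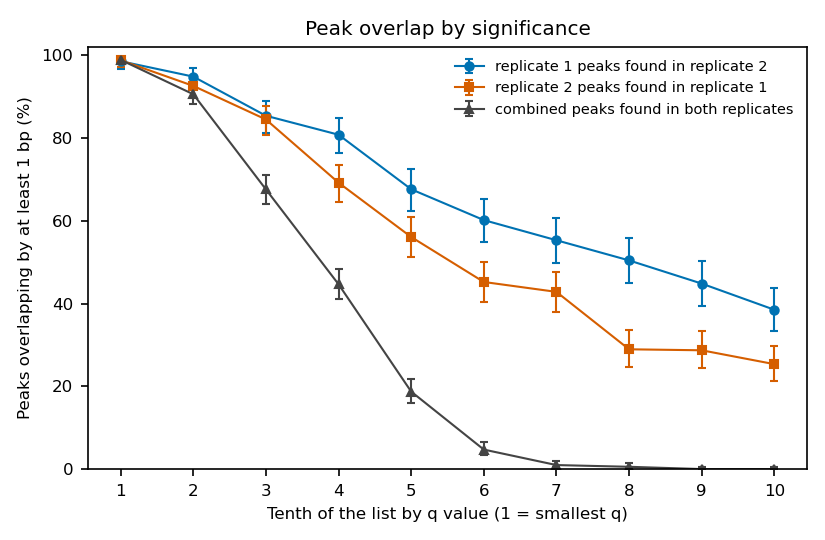
Share of peaks (percent, vertical axis) that overlap by at least 1 bp, for 10 equal parts of a list ordered from smallest to largest q (horizontal axis), for replicate 1 peaks in replicate 2, replicate 2 peaks in replicate 1 and combined peaks in both; bars are exact 95% binomial intervals. The lines start at 98.6%, 98.8% and 98.9% in the part with the smallest q, and the combined line is at 0 in the last 2 parts.

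Regions with a small q in 1 replicate tended to have a small q in the other. Over 2348 pairs of peaks that were each other's largest overlap, −log10 q correlated with Spearman's rho = 0.62 (500 kb block interval 0.59 to 0.65) and Pearson's r = 0.80 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). These are correlations across peaks called in both lists, and peaks are not independent replicates. Without the 2 strongest pairs r was 0.75. Within single chromosomes rho was lowest on X, at 0.57, and highest on III, at 0.69; all 7 tests had a Benjamini-Hochberg adjusted permutation p of 1e-05. The replicate 1 value was the higher in 1521 of the 2348 pairs (64.8%), and the median excess was 0.81 in −log10 q. On chromosome I this excess was 2.13, against 0.26 on X, 0.33 on II, 0.41 on V, 1.01 on III and 1.32 on IV.

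**Figure D2:**
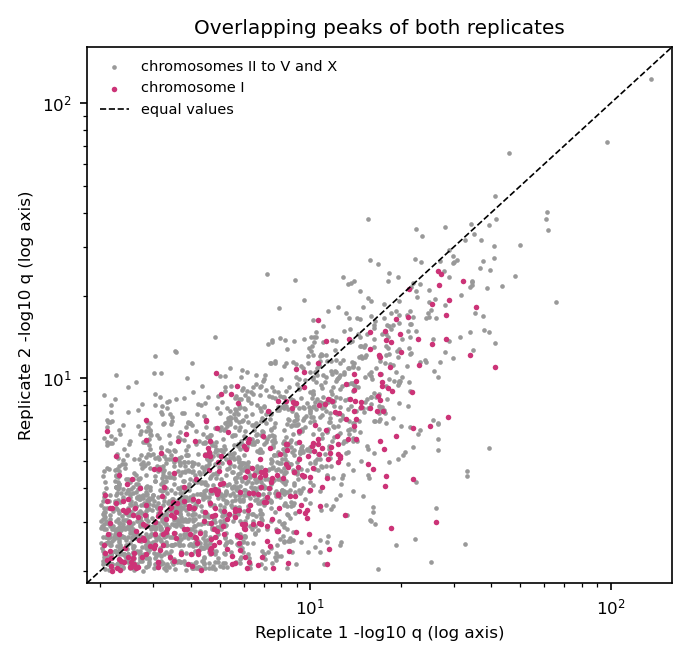
Each point is a pair of overlapping peaks, with −log10 q in replicate 1 (horizontal, log axis) and in replicate 2 (vertical, log axis); chromosome I pairs are coloured and the dashed line marks equal values. Of the 370 chromosome I pairs, 78.4% had the higher value in replicate 1, compared with 64.8% of all pairs.

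The third question was how much of the combined list each replicate carried by itself. Of the 7213 combined peaks, 2358 (32.7%, exact binomial interval 31.6 to 33.8%) overlapped peaks of both replicates, 1054 (14.6%) of replicate 1 alone, 1371 (19.0%) of replicate 2 alone, and 2430 (33.7%) of neither. Independent shifts of both replicate lists gave a mean of 0.143% ± 0.044 (SD of 1000 shifts) of combined peaks in both; no p-value is given, because the libraries behind the combined list are not given in the sources used here. Regions in both replicates were wider and more significant, with a median width of 469 bp and a median q of 2.34e-11. Regions in neither had a median width of 218 bp and a median q of 0.00237. All 2360 replicate 1 peaks and all 2396 replicate 2 peaks that the replicates shared were in the combined list. Of the peaks seen in 1 replicate only, 95.6% of the 1128 in replicate 1 and 79.3% of the 1789 in replicate 2 were there. Wider peaks meet the 1 bp rule more easily, and the combined list may share reads with both replicates. The differences in width and q and the overlaps with the combined list may therefore be built in.

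Chromosome I stood apart in the combined list. On it, 772 of 1528 combined peaks (50.5%, exact binomial interval 48.0 to 53.1%) were found in neither replicate, against 1658 of 5685 (29.2%, 27.99 to 30.4%) on the other chromosomes, where the single-chromosome shares ran from 26.96% on III to 33.2% on X. Of the combined peaks on chromosome I, 32.9% overlapped a replicate 2 peak, against 56.8% elsewhere. Overlap with replicate 1 was also lower there, at 40.6% against 49.1%. Leaving chromosome I out raised the share of combined peaks found in both replicates to 35.0%.

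The last comparison was the distribution over chromosomes. Chromosome III had the most peaks per Mb in all 3 lists, with 59.5 in replicate 1, 69.0 in replicate 2 and 108 in the combined list. Chromosome X had the fewest peaks per Mb in all 3, with 21.6, 33.4 and 50.8, but chromosome V was close to it, with 25.2, 33.6 and 53.9. Peak density on X was 0.57 of that on the 5 autosomes in replicate 1 (block interval 0.50 to 0.66), 0.77 in replicate 2 (0.69 to 0.86) and 0.66 in the combined list (0.60 to 0.74), each lower than uniform placement gave (two-sided permutation p = 0.001, the smallest that 1000 draws can give). The uniform draws place each peak independently and so ignore clustering. The block intervals are drawn within chromosomes and leave out the spread between autosomes, from 25.2 on V to 59.5 on III in replicate 1. A deficit particular to X is therefore not shown. Without chromosome I the combined ratio was 0.72. The chromosomes taking the most combined peaks were I with 1528 and III with 1491. In replicate 2 chromosome I held 523, fewer than any other chromosome. Per Mb it was not the lowest there, at 34.7 against 33.6 on V and 33.4 on X.

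Along the chromosomes, the left of 3 equal parts of III held 43.7% of that chromosome's peaks in replicate 1 and 47.8% in replicate 2, and the left part of IV held 45.1% and 43.8%. On chromosome III the bin from 1 to 2 Mb held 141 replicate 1 peaks, 163 replicate 2 peaks and 214 combined peaks, the most of any 1 Mb bin in each list. The middle parts of the autosomes together held 29.0% of autosomal peaks in replicate 1, 28.02% in replicate 2 and 28.6% in the combined list, against 33.3% for even placement. Uniform placement gave a two-sided permutation p of 0.001 in each list, but resampling 500 kb blocks gave intervals of 22.4 to 36.3%, 21.4 to 35.4% and 22.02 to 35.9%, all of which include 33.3%. The number of centre blocks varied between these draws, which widens the intervals even where peaks are evenly spread. They therefore cannot decide whether the lower share in the centres exceeds what clustering gives.

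**Figure D3:**
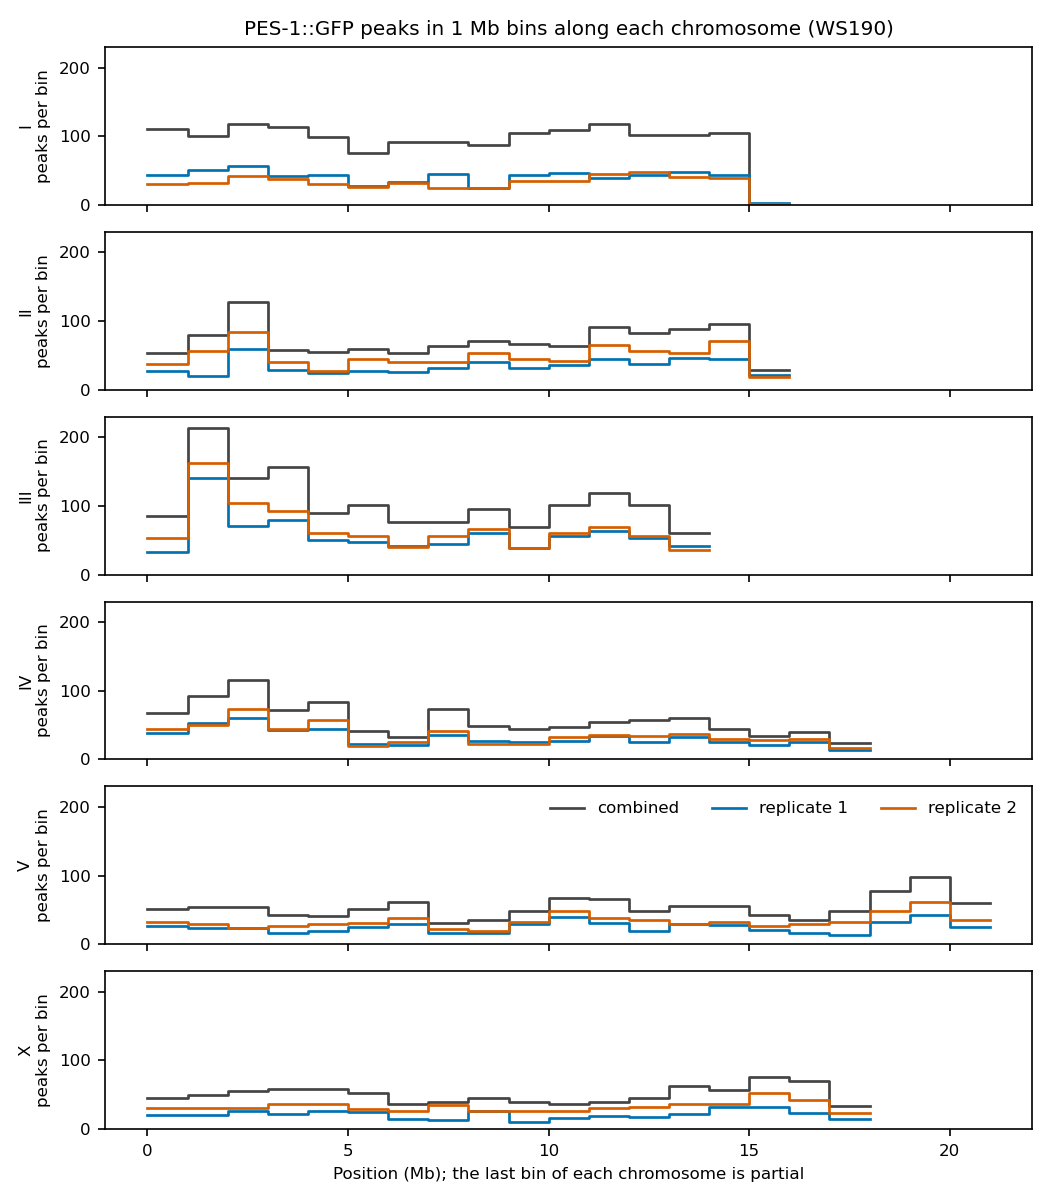
Number of peaks (vertical axes) in 1 Mb bins along each of the 6 chromosomes (horizontal axis, Mb, WS190) for the combined list and both replicate lists. The bin from 1 to 2 Mb on chromosome III is the highest in each list, at 214, 141 and 163 peaks. On all 6 chromosomes the combined line lies above both replicate lines in every full bin.

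**Figure D4:**
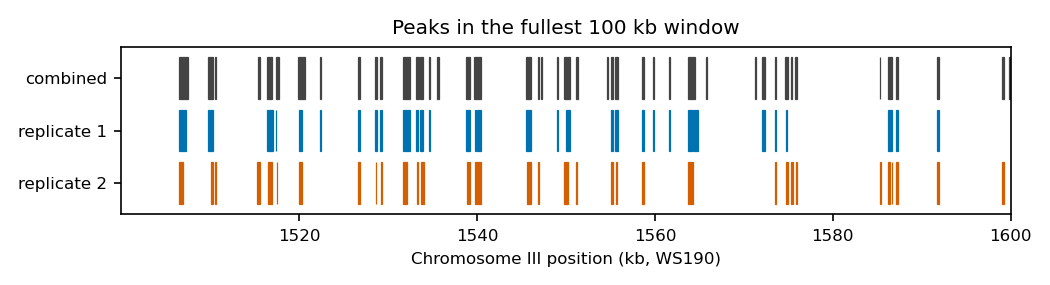
Peaks of the combined list, replicate 1 and replicate 2 (rows) along chromosome III from 1500001 to 1600000 (horizontal axis, kb, WS190), each bar being a peak drawn to its width. The window holds 44 combined, 32 replicate 1 and 33 replicate 2 peaks, the most of any 100 kb window in each list.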

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

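All tests in this part were chosen after the peak lists had been seen. The share of peaks on a chromosome differed between the replicate lists on 4 of 6 chromosomes, judged by block intervals at a level of 99.2%, which adjusts 95% intervals for 6 comparisons; each replicate is 1 list, so the difference is between lists. The odds of a peak lying on chromosome I were 0.64 times as high in replicate 2 as in replicate 1 (interval 0.57 to 0.72), with 523 of 4185 peaks (12.5%) against 634 of 3488 (18.2%). The odds ratios were 1.22 on II (1.08 to 1.41), 1.13 on V (1.03 to 1.25) and 1.33 on X (1.17 to 1.53), and those on III and IV, at 0.96 and 0.92, had intervals that include 1. Shares of a list sum to a whole, so a low share on I raises the others. Without chromosome I the ratio on X was 1.24 (1.09 to 1.43), while those on II and V, at 1.13 and 1.05, had intervals that include 1, and III and IV fell to 0.87 and 0.85 with intervals below 1.

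For the low share of chromosome I in replicate 2, a chromosome-wide difference of q values was weighed over regions called in both lists. Replicate 1 exceeded replicate 2 in −log10 q by 1.49 more on chromosome I than on the other chromosomes (block interval 0.91 to 1.93), so such a difference is a candidate explanation. Every listed peak has one of these same q values, under 0.01. The excess may therefore restate the low share and is not separate support. Over the 6 chromosomes the median excess, at 2.13 on I, 1.32 on IV, 1.01 on III, 0.41 on V, 0.33 on II and 0.26 on X, ran in the reverse order of the odds ratios. That order was not tested, and it too rests on the same q values. What produced the difference was not tested, and depth per list is unknown. A difference in binding between the worm populations would also move both values and stays open, as no biological explanation was tested.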

How the results depend on the processing

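The overlap of the replicates in either direction, the correlation of their scores, the lower density on X and the lower share in the autosomal centres kept their direction and their side of p = 0.05 under every alternative run, and 2 of these (without chromosome I, and only peaks of at least 50 bp) were added after seeing the data. Replicate 1 peaks found in replicate 2 ranged from 58.2% to 71.0%, replicate 2 peaks found in replicate 1 from 48.5% to 63.0%, rho from 0.61 to 0.65 and the X ratio from 0.53 to 0.77. The middle 50% of each autosome held 44.5% of peaks, below the 50% of even placement. The other centre shares ran from 27.7% to 29.3%, below 33.3%. The uniform draws behind the X and centre p-values ignore clustering. Block intervals of the centre share included 33.3% in each list, but the number of centre blocks varied between draws, which widens them. Neither the uniform draws nor these intervals decide the question, so the lower centre share is not established. The share of combined peaks found in both replicates, which has no test, moved beyond its binomial interval under every alternative but an overlap of at least 50% of the shorter peak, which gave 32.6%. It was 26.9% at 50% reciprocal overlap, 34.2% in the 50% of each list with the smaller q, 35.0% without chromosome I and 34.3% for peaks of at least 50 bp. Asking for 1 replicate in place of both gave 47.3% without replicate 2 and 51.7% without replicate 1, by the construction of that alternative; for the others the cause was not tested. Promoter, gene list and motif results, with their alternatives, were not run because a genome and annotation of the build were not used here, and the correlation with another score was not run because q is the lists' only score. Depth limits what a missing peak means, since the lists give no read counts.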

Other observations

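Of the tests in this part, those of crowding and of replicate 2 alone were chosen after the result was seen. Peaks were unevenly crowded, and most of the 12 fullest combined windows of 100 kb lay in the left of 3 equal parts of chromosome III. Peaks were not limited to such windows, since 29 of 1004 windows held no combined peak. The fullest 100 kb window of every list was chromosome III from 1500001 to 1600000, with 32 peaks in replicate 1, 33 in replicate 2 and 44 in the combined list, against medians of 3, 4 and 6 over 1004 windows. The window from 1900001 to 2000000 on the same chromosome was second in every list, with 24, 29 and 32 peaks. Among the 12 fullest combined windows, chromosome II from 1300001 to 1400000 held 9 replicate 1 and 24 replicate 2 peaks, and chromosome I from 2600001 to 2700000 held 12 and 4. Uniform placement of the same number of peaks on each chromosome reached the fullest window in 0 of 1000 draws for either replicate, the highest draws being 19 and 22. With the fullest window left out, 0 of 1000 draws reached the variance of the remaining windows, so the crowding was not confined to 1 window. Gene density, repeats and copy number were not examined, since no genome of the build was used.

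On chromosome I, the share of combined peaks held by neither replicate list was 21.4 percentage points above that on the other chromosomes. Standardised to 10 strata of combined q, the excess was 26.0 points (block interval 24.2 to 27.8). This argues against weak combined q values as the whole cause. It cannot decide on weakness in reads, because combined q was itself shifted on I, as given below. Split peaks are argued against too, since 15.2% of these peaks lay within 500 bp of another combined peak (interval 12.1 to 18.05), against 11.4% elsewhere. In regions found in all 3 lists, combined −log10 q exceeded the sum of the replicate values by 4.20 more on I than elsewhere (4.03 to 4.50). The median excess was 4.33 on I, while on the other chromosomes it ran from −0.04 on X to 0.33 on III. Low replicate 2 values alone would not give this shift, since combined minus replicate 1 was higher on I by 3.99 (3.27 to 4.82). A hypothesis is that this shift may bring regions absent from both replicate lists past the threshold; neither what produced it nor a biological explanation was tested.

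The peaks in this paragraph were chosen after their values were seen. The peak of replicate 2 with the second smallest q, on chromosome I from 15064011 to 15067641 with q = 3.11e-83, had no counterpart in either other list, and the last combined peak on that chromosome ended at 14994651. The 2 replicate 1 peaks lying wholly past that point, at 15013946 to 15014082 and 15034001 to 15034199, had q values of 3.30e-08 and 3.07e-14. The 5 most significant replicate 1 peaks with no overlapping replicate 2 peak were all on chromosome I, led by 7866933 to 7868573 with q = 1.11e-21, and 4 of them, that one included, were in the combined list. Of all 87 such replicate 1 peaks with q under 1e-06, 26 were on chromosome I, which held 18.2% of all replicate 1 peaks. Of the 25 replicate 2 peaks with no overlapping replicate 1 peak at that limit, 3 were, near the 12.5% of all replicate 2 peaks on that chromosome. Both percentages cover peaks at any q. In replicate 1 the median q was smaller on chromosome I, at 5.08e-05, than over the list, at 8.51e-05. Set against 18.2%, the excess on chromosome I may therefore be overstated. Peaks under 20 bp numbered 212 in the combined list, 96 in replicate 2 and 8 in replicate 1, and of the 212, 3 overlapped a replicate 1 peak and 29 a replicate 2 peak.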
